A study of Homo sapiens with 6 samples.

How the data were processed

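RNA was sequenced from 6 samples of BEAS-2B cells, an established human bronchial epithelial line immortalised with an adenovirus-SV40 hybrid virus. Per the labels, 3 samples received 6 Gy of X-rays from a linear accelerator (6 MV photons at 300 cGy per minute) and 3 received no radiation. The time between irradiation and RNA extraction is not given in the sources used here. Groups were taken from the treatment label of each sample and replicate numbers from the sample titles. No label says that the replicates were separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical.

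The authors deposited 1 table for the whole series, with 11549 protein-coding genes. Per the file headers, it holds an FPKM value (fragments scaled to gene length and mapped fragments) per gene and sample, and the authors' mean of log2(FPKM + 1) in each group. It also holds the authors' log2 fold change, the fold change made from it as a ratio, the p-value of an F-statistic and a q-value. The deposited group means and log2 fold changes were recomputed from the FPKM columns and differed by at most 4.9e-09 and 2.6e-08. Per the submitters' processing notes, Bowtie 0.12.2 and the mouse builds mm8 and mm10 were used, although the gene identifiers are human. How the human FPKM values were made, and with which annotation and filters, is not given in the sources used here. In every listed gene at least 1 group had a mean FPKM of 0.500 or more.

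No genome build is named in the table. Of 11491 nuclear genes also found in GENCODE release 29 on GRCh38, 77 had identical coordinates, so the positions printed are those of the deposited table and no other build was mixed in. The symbols of 19 genes were stored as dates, and these were restored from the gene identifiers. Of the 11549 identifiers, 11486 matched the gene name table. Genes that overlap another listed gene on the same strand by at least 1 base (861 genes) were marked, since FPKM estimates can divide fragments between them.

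FPKM values are not counts, and the depth of the libraries is unknown. The listed values are fractional estimates: the smallest above 0 was 8.78e-07, and 4 values lay below what 1 fragment would give even in a very deep library, so whole reads could not be recovered. No counting interval or detection floor is given for this reason. The FPKM totals over the listed genes were 213819 to 231858 per library. Where FPKM is exactly 0, the gene is only said to be listed at 0.

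The comparison of irradiated and control samples was made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) of the 10526 genes whose mean FPKM over all 6 samples was at least 1, without trend or robust options and without a block. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and their SE is limma's moderated one. Ratios are those of mean FPKM values. The comparison was also run on simulated data with the real means and spreads (10526 genes, 200 of them changed, 5 simulations). It recovered 23.6% of genes changed by a log2 value of 0.5, 71.2% at 1, 88.8% at 1.5 and 94% at 2. Of its calls, 5.17% were false. The simulated noise was independent between genes. Deviations that many genes of a real library share, such as those along GC content, are therefore not covered by these rates.

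The test, the sample grouping, 25 gene lists, the rule for named genes and the other settings were fixed before the data were examined. The lists cover p53 targets, DNA replication, mitosis, DNA damage signalling and repair, replication-dependent histones, NRF2 targets, antioxidant enzymes and sources of reactive oxygen species, the type I interferon response, inflammatory cytokines and NF-kB targets, secreted proteases and senescence factors, TGF-beta, matrix and mesenchymal genes, epithelial junctions and keratins, apoptosis, the unfolded protein and integrated stress responses, immediate early genes, heat shock proteins, cholesterol synthesis, glycolysis and hypoxia, the nuclear-encoded respiratory chain, mitochondrially encoded genes and cytosolic ribosomal proteins. They also hold markers of secretory, ciliated and alveolar cells, of fibroblasts, of endothelium and of leukocytes. Lists with at least 5 tested members (21 of the 25) were tested with limma's camera at its preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over those 21 lists. At this preset, camera sets a list's genes against the other genes and takes genes as nearly independent. Its p-values therefore do not measure the spread between samples. Other splits of the 6 samples called up to 11 lists, against 10 for the real one. Members were also counted one by one, adjusted over all genes and adjusted over the list alone. The rule named the 10 largest rises and 10 largest falls among changed genes whose groups did not overlap, up to 4 members of each list with the smallest p, and 15 fixed genes. Some genes that the rule names are not reported here.

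The other settings fixed in this way were pseudocounts of 0.1 and 0.01, no filter and a filter at a mean FPKM of 0.1, quantile normalization, median centring, limma with a trend and robust fit, the replicate number as a block, each of the 6 libraries left out in turn, an added fold of at least 2, the authors' deposited q-values, and for lists an estimated correlation and fry. Unlike camera, which compares a list with the other genes, fry tests whether a list's genes move on balance 1 way, so its p answers another question. Alternatives that need counts were not run because the table holds none. After the data were seen, 2 gene lists, limma's sample weights and a correction for GC content were added. For the last, each library's deviation from the gene's mean was fitted on the GC content of the gene's longest protein-coding transcript in GENCODE release 29 (natural spline, 5 degrees of freedom) and removed, in the 10462 tested genes with such a transcript. Groups of 3 were not tested for outlying samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.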

Results

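The transcriptome of BEAS-2B bronchial epithelial cells was measured in 3 irradiated samples (6 Gy of X-rays) and 3 unirradiated control samples as FPKM values of 11549 protein-coding genes. The comparison asks which genes differ after irradiation, and the title of the study names oxidative stress in radiation-induced lung injury as its subject. FPKM totals lay between 213819 and 231858 per library and the read depth is unknown. Mitochondrially encoded genes made up 12.2%, 15.7% and 13.9% of the FPKM total in irradiated replicates 1 to 3, and 24.1%, 15.2% and 16.7% in control replicates 1 to 3. Across genes, control replicate 1 correlated with the other control libraries at r = 0.969 and 0.964, against 0.983 between those others and 0.975 to 0.983 among the irradiated libraries. Genes are not independent replicates in these correlations.

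The largest rises in irradiated cells included CCND1, MMP1, FOSL1, CDKN1A and GDF15. CCND1, which encodes cyclin D1 (ENSG00000110092.3_2, chromosome 11, 69455855 to 69469242), reached 58.9 ± 1.36 FPKM against 6.71 ± 0.939 in controls (mean ± SD, n = 3 per group here and below), a ratio of 8.78. Its log2 fold change was 2.97 ± 0.119 (SE, limma adjusted p = 0.000238). MMP1, an interstitial collagenase (ENSG00000196611.4_2, chromosome 11, 102660651 to 102668891), was at 9.55 ± 2.27 against 0.407 ± 0.145 FPKM, a log2 fold change of 2.89 ± 0.169 (limma adjusted p = 0.000718). FOSL1, a partner of JUN in the AP-1 transcription factor, was at 74.4 ± 3.66 against 14 ± 3.25 FPKM. CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases (ENSG00000124762.13_2, chromosome 6, 36644237 to 36655116), was at 111.9 ± 10.1 against 25.8 ± 7.58 FPKM, a ratio of 4.33 (log2 fold change 2.11 ± 0.218, limma adjusted p = 0.00629). GDF15, a stress-induced secreted factor of the TGF-beta family, was at 7.61 ± 1.15 against 0.917 ± 0.359 FPKM, a ratio of 8.31. The other 5 of the 10 largest rises were those of CSF2 (the cytokine GM-CSF), RGS4 (a regulator of G-protein signalling), ESM1 (a secreted proteoglycan), PRSS23 (a secreted serine protease) and ELK3 (an ETS transcription factor), with log2 fold changes of 2.50, 2.37, 2.35, 2.19 and 1.97. All 10 passed the threshold without each of the 6 libraries in turn, CDKN1A with an adjusted p of up to 0.047 and CSF2 of up to 0.0339.

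**Figure D1:**
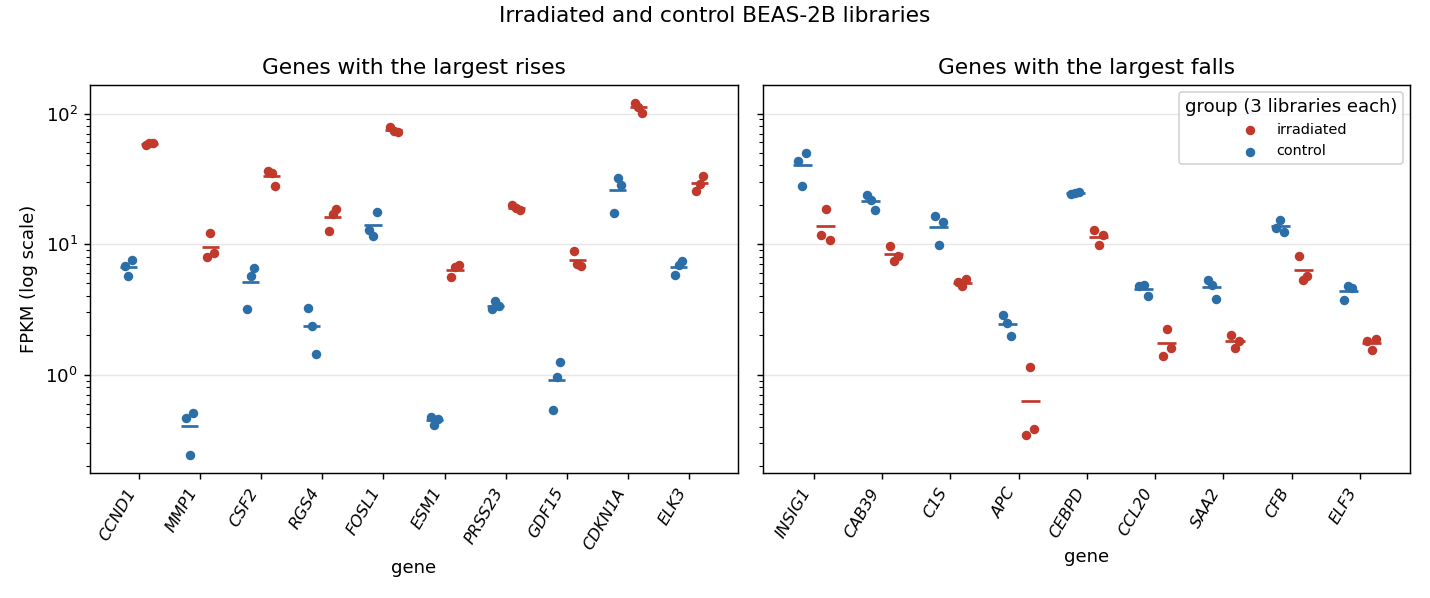
FPKM (log axis) of the genes named for the largest rises and the largest falls; each point is 1 library, lines are group means, red is irradiated and blue control (3 libraries each). In each gene the groups do not overlap, for example CCND1 at a mean of 58.9 against 6.71 FPKM and CEBPD at 11.4 against 24.7.

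The largest falls were smaller than the largest rises. CEBPD, a transcription factor of the acute-phase response (ENSG00000221869.4_2, chromosome 8, 48649471 to 48651648), was at 11.4 ± 1.43 against 24.7 ± 0.4 FPKM in controls, 2.16 times lower (log2 fold change -1.05 ± 0.116, limma adjusted p = 0.00858). CAB39, a scaffold of the kinase LKB1, was at 8.38 ± 1.11 against 21.3 ± 2.79 FPKM. INSIG1, which restrains sterol synthesis and is itself induced by SREBP, was at 13.7 ± 4.26 against 40.2 ± 11.1 FPKM (log2 fold change -1.49 ± 0.262, limma adjusted p = 0.0437). C1S and CFB, both complement proteases, had log2 fold changes of -1.24 and -1.01, the chemokine CCL20 -1.02, the acute-phase gene SAA2 -1.01, the epithelial transcription factor ELF3 -0.97 and the Wnt regulator APC -1.11. C1S and SAA2 overlap another listed gene on the same strand, and SAA2 has a near-identical copy in SAA1, so their values are uncertain. Of the falls named here, only that of CEBPD passed without each of the 6 libraries in turn. CAB39 lost its call without irradiated replicate 2 (adjusted p = 0.0555). INSIG1, APC and CFB passed in 1 of the 6 such fits (adjusted p up to 0.178, 0.173 and 0.141), C1S, SAA2 and ELF3 in 2 (up to 0.127, 0.108 and 0.0895) and CCL20 in 3 (up to 0.0929). APC also lost its call with a pseudocount of 0.1 (adjusted p = 0.066) and after correction for GC content (0.0521), and INSIG1 with a pseudocount of 0.1 (0.0539).

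Across 10526 tested genes, limma called 184 changed at an adjusted p under 0.05, 144 higher and 40 lower in irradiated cells, with a median absolute log2 fold change of 0.86. All 184 had groups that did not overlap, which a call from 3 against 3 samples makes likely in itself. So did 30.0% of all tested genes. Chance gives 10% per gene, but genes are not independent, so this share is no test against chance. The authors' deposited table lists 69 genes with a q-value under 0.05, 58 higher and 11 lower, of which 42 are among the 184. Of the others, 9 lay outside the filter on low values and were not tested here, and 18 were tested and not called. The count fell without irradiated replicate 1 (62 genes), 2 (40 genes) or 3 (65 genes) and without control replicate 2 (59 genes) or 3 (97 genes), and was 174 without control replicate 1. Fold changes followed the GC content of the transcript (Spearman's rho = 0.56 across genes). After a correction for GC content, chosen after seeing the data, 412 genes were called, 250 higher and 162 lower, which moved the share of higher calls from 78.3% to 60.7%; 162 genes were called in both.

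**Figure D2:**
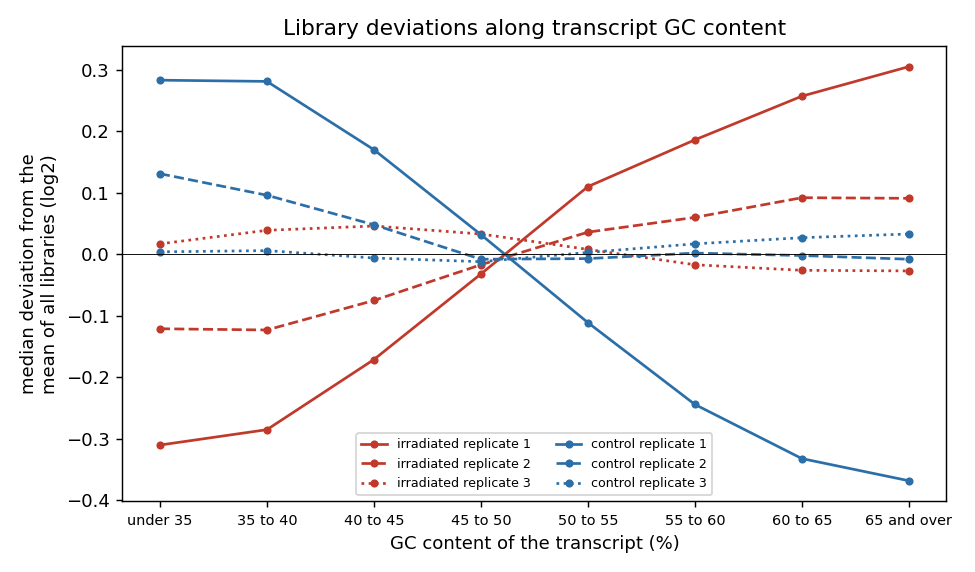
Median deviation of each library from the mean of all 6 libraries (log2, vertical axis) for genes binned by transcript GC content (percent, horizontal axis); each line is 1 library, red irradiated and blue control. Between the bins under 35% and from 65% GC, irradiated replicate 1 goes from -0.310 to 0.305 and control replicate 1 from 0.283 to -0.368.

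Targets of p53, the transcription factor activated by DNA damage, lay higher as a list in irradiated cells. The activity of the p53 protein itself was not measured. Of 34 tested members, 10 rose and 0 fell (18 and 0 adjusted over the list alone), and 31 lay above 0, with a median log2 fold change of 0.52. The camera test called the list higher (adjusted p = 1.24e-11), and of the 21 lists fixed and tested it was the only one called with an estimated correlation (adjusted p = 0.0342). Besides CDKN1A and GDF15, the antiproliferative gene BTG2 was at 14.4 ± 0.769 against 6.58 ± 0.807 FPKM, the nuclease AEN at 14.9 ± 1.71 against 6.33 ± 1.02, and MDM2, the ubiquitin ligase that limits p53, at 13.1 ± 2.40 against 5.60 ± 1.20 (log2 fold changes 1.02, 1.12 and 1.09, limma adjusted p = 0.00877, 0.0156 and 0.0319). BTG2 and AEN lost their calls without irradiated replicate 1 or 2 (adjusted p up to 0.0682 and 0.0937), and MDM2 without any library but control replicate 1 (up to 0.13). Without irradiated replicate 1, 2 or 3, 2, 2 and 4 members rose, without control replicate 2 or 3, 5 each, and 9 without control replicate 1. None of the 34 members (0 genes) had a q-value under 0.05 in what the authors deposited.

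Inflammatory cytokines and NF-kB targets were called higher as a list (camera adjusted p = 2.87e-07), with 8 of 24 members up and 1 down (13 and 1 adjusted over the list alone). With an estimated correlation the list was not called (adjusted p = 0.292). Over all genes, 4 members rose without irradiated replicate 1, 3 without irradiated replicate 2 or 3 or control replicate 2 or 3, and 7 without control replicate 1. IL1B was at 18.8 ± 1.84 against 5.30 ± 0.791 FPKM (log2 fold change 1.65, limma adjusted p = 0.00201) and IL11 at 10.99 ± 2.26 against 3.07 ± 0.428 (1.54, 0.00725), while CCL20 was the member that fell. IL6 was at 17.5 ± 1.63 against 10.95 ± 0.362 FPKM (log2 fold change 0.63, limma adjusted p = 0.0376) and did not pass when any 1 library was left out (adjusted p 0.0627 to 0.149). CXCL8 was at 208 ± 13.3 against 107.6 ± 25.0 FPKM with a limma adjusted p of 0.051, and passed without control replicate 1 (0.0304), with quantile normalization (0.0354) and after correction for GC content (0.0363).

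Secreted proteases and senescence factors were called higher (camera adjusted p = 2.13e-05), with 6 of 23 members up and 1 down (13 and 5 adjusted over the list alone). The adjusted p was 0.116 with an estimated correlation. The member that fell was CDKN2B (log2 fold change -0.78). Of the 23 members 17 lay above 0 and 6 below. Those below include HMGB2 (-0.92), LMNB1 (-0.46), HMGB1 (-0.405) and CDKN2A (-0.03), none of them called over all genes. Over all genes, 4 members rose without each library other than control replicate 1, and 5 without that one. Among these fits a fall was called only without control replicate 1. Beside MMP1, the protease inhibitor SERPINB2 was at 4.77 ± 0.675 against 0.583 ± 0.152 FPKM, the plasminogen activator PLAT at 36.5 ± 1.01 against 9.70 ± 1.83, and the EGF-receptor ligand AREG at 5.75 ± 0.281 against 1.70 ± 0.279 (log2 fold changes 1.86, 1.82 and 1.33, limma adjusted p = 0.00127, 0.00197 and 0.00247). Whether the unnamed genome build holds a near-identical copy of AREG was not checked, so the value of AREG is uncertain. TGF-beta, matrix and mesenchymal genes were not called as a list (camera adjusted p = 0.093), except without control replicate 3 (adjusted p = 0.03). In that list 2 of 31 members rose (5 up and 2 down adjusted over the list alone), among them ACTA2, a smooth-muscle actin, at 5.12 ± 0.631 against 1.39 ± 0.16 FPKM. Over all genes 1 member rose without irradiated replicate 1 or 2, and 3 without control replicate 1. LOX, which crosslinks collagen, had a log2 fold change of 0.66 (limma adjusted p = 0.0576) and passed without control replicate 1 (0.0304) and after GC correction (0.0162). TGFBR2 had 0.48 (limma adjusted p = 0.0937) and passed after GC correction (0.0371).

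Immediate early genes were called higher (camera adjusted p = 0.000121), with 5 of 19 members up and 0 down (8 and 0 adjusted over the list alone). With an estimated correlation the adjusted p was 0.292. The median log2 fold change of 0.47 was 0.29 without irradiated replicate 3 and 0.31 after GC correction. After that correction 8 members were higher and 2 lower adjusted over the list alone. Of the 19 members 14 lay above 0 and 5 below. Those below 0 include MYC (-1.25), JUND (-0.51) and EGR1 (-0.41), none of them called. The members that rose include FOSL1 and 3 phosphatases induced by and acting on MAP kinases, DUSP4, DUSP5 and DUSP6, with log2 fold changes of 1.41, 1.05 and 1.44 (limma adjusted p = 0.00127, 0.00629 and 0.002). DUSP6 was at 3.53 ± 0.439 against 0.664 ± 0.0899 FPKM, and DUSP5 lost its call without irradiated replicate 2 (adjusted p = 0.0515), where 3 members rose.

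Genes of cholesterol synthesis and uptake were called lower (camera adjusted p = 8.3e-08; adjusted p = 0.0848 with an estimated correlation). Of 21 tested members, 6 fell and 0 rose (12 and 0 adjusted over the list alone), and 20 lay below 0. HMGCS1, which makes HMG-CoA, was at 6.13 ± 0.385 against 11.5 ± 1.39 FPKM (log2 fold change -0.81, limma adjusted p = 0.0224), the squalene epoxidase SQLE at 21.2 ± 4.04 against 38.5 ± 1.25 (-0.85, 0.0371) and the isomerase IDI1 at 24.1 ± 2.33 against 38.8 ± 3.04 (-0.67, 0.0437). Over all genes, 1 member fell without control replicate 1 or 2 or irradiated replicate 3, and 0 without any of the other 3 libraries. HMGCS1 passed in 1 of the 6 fits that left out 1 library (adjusted p up to 0.13), SQLE in 1 (up to 0.17) and IDI1 in 0 (up to 0.179).

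**Figure D3:**
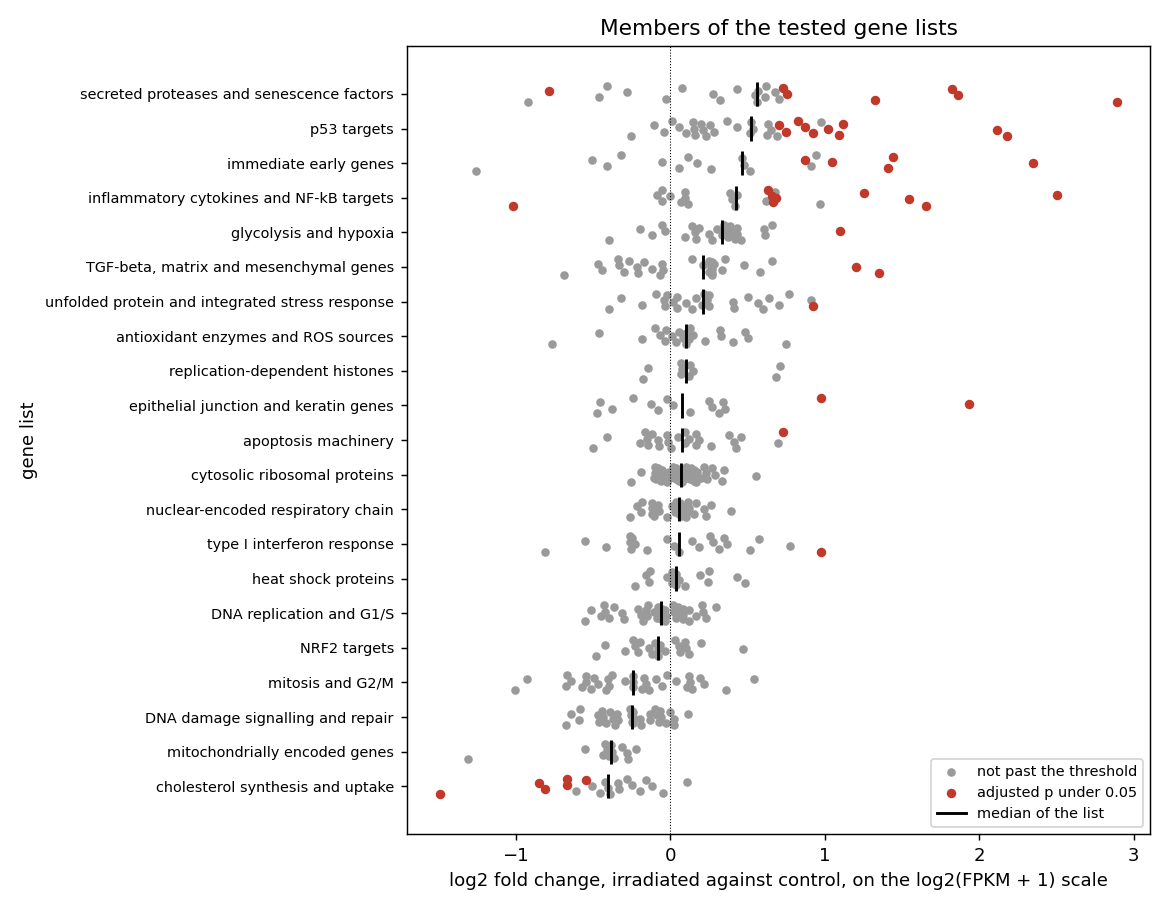
Log2 fold change (irradiated against control, on the log2(FPKM + 1) scale, horizontal axis) of each tested member of the 21 tested gene lists (vertical axis, sorted by median); red points passed an adjusted p under 0.05 over all genes, and black lines are medians. The p53 list has a median of 0.52 and the cholesterol list of -0.40.

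Genes of mitosis and of DNA damage signalling and repair lay lower as lists, without single members past the threshold. Of 35 mitotic genes 26 lay below 0 (median log2 fold change -0.24, camera adjusted p = 0.00103), and of 35 repair genes 31 did (median -0.25, camera adjusted p = 1.79e-05). With an estimated correlation both had an adjusted p of 0.292. limma called 0 members of either list over all genes or adjusted over the list alone, against 15 and 12 at an unadjusted p under 0.05 and 0 and 0 in the authors' deposited table. After GC correction, 1 mitotic gene fell over all genes, 1 was higher and 12 lower adjusted over the list alone, and 0 repair genes passed either way. The medians were then -0.24 for the mitotic and -0.17 for the repair genes. Their mean GC contents were 45.5% and 44.5%, against 49.5% over all tested genes. KIF11, a spindle motor, was at 24.9 ± 4.15 against 40.3 ± 6.35 FPKM (log2 fold change -0.68, limma adjusted p = 0.0976; 0.0371 after GC correction), and CENPE at 5.26 ± 0.894 against 12.1 ± 5.14. AURKA went the other way at 90.3 ± 4.13 against 62.4 ± 11.9 FPKM (limma adjusted p = 0.127). CCNB1 had 160 ± 3.53 against 155.7 ± 4.56 FPKM and PLK1 34.97 ± 3.27 against 29.9 ± 3.04 (limma adjusted p = 0.818 and 0.329); the log2 value of CCNB1 was 0.04, and -0.06 after quantile normalization. The repair helicases BRIP1 and BLM had log2 fold changes of -0.68 and -0.59 (limma adjusted p = 0.115 and 0.131).

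DNA replication genes were not called as a list (camera adjusted p = 0.0608, median log2 fold change -0.06). The list was called lower without control replicate 1 (adjusted p = 0.0106), without irradiated replicate 1 (0.00767), with quantile normalization (0.0306) and after GC correction (0.0013). The median was -0.10 without irradiated replicate 1 or control replicate 1, and -0.02 without irradiated replicate 2. Of 40 members limma called 0 over all genes and 2 lower adjusted over the list alone, with 8 at an unadjusted p under 0.05 and 0 in the authors' deposited table. RFC4 and MCM6 had log2 fold changes of -0.55 and -0.51 (limma adjusted p = 0.0591 and 0.0803), and RFC4 passed after GC correction (0.0182). MCM2 was at 44.7 ± 7.12 against 44.0 ± 7.52 FPKM (limma adjusted p = 0.938), and its log2 value of 0.03 became -0.01 with quantile normalization and -0.15 after GC correction. Replication-dependent histones were not called (camera adjusted p = 0.21), and limma called 0 of 10 members, with 2 at an unadjusted p under 0.05 and 0 in the authors' deposited table. HIST1H2BJ had 2.21 ± 0.862 against 0.952 ± 0.0508 FPKM (limma adjusted p = 0.123).

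The genes of the oxidative stress response, the subject named in the study's title, showed no list past the threshold. NRF2 targets had a median log2 fold change of -0.08 (camera adjusted p = 0.234), and were called lower without control replicate 1 (adjusted p = 0.00746; median -0.13). The median was -0.025 without irradiated replicate 3, and 0.02 without control replicate 2 or 3, where the mean stayed below 0. limma called 0 of 22 members over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 0 in the authors' deposited table. After GC correction, 2 members fell over all genes, and 1 was higher and 3 lower adjusted over the list alone. NQO1 was at 37.3 ± 5.50 against 41.8 ± 10.9 FPKM (limma adjusted p = 0.726), HMOX1 at 7.22 ± 1.54 against 6.40 ± 2.55 (0.685), SRXN1 at 42.5 ± 1.96 against 30.5 ± 3.33 (0.0991) and TXNRD1 at 70.9 ± 10.9 against 98.4 ± 4.24 (0.13). The log2 value of HMOX1 was 0.20, and -0.10 without control replicate 1. Antioxidant enzymes and sources of reactive oxygen species had a median of 0.10 (camera adjusted p = 0.153), which was 0.05 without control replicate 1, 0.06 without irradiated replicate 1 and 0.17 without control replicate 2. limma called 0 of 23 members over all genes and 2 higher and 1 lower adjusted over the list alone, with 4 at an unadjusted p under 0.05 and 0 in the authors' deposited table. After GC correction, 1 rose and 1 fell over all genes. The mitochondrial superoxide dismutase SOD2 was at 4.79 ± 0.601 against 6.92 ± 0.529 FPKM, catalase (CAT) at 17.9 ± 2.25 against 18.3 ± 2.50 and the metallothionein MT2A at 191.6 ± 23.1 against 135.8 ± 5.75 (limma adjusted p = 0.115, 0.906 and 0.1). The log2 value of CAT was -0.03, and lay above 0 after GC correction (0.015) and without irradiated replicate 1 or control replicate 2 or 3.

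Genes of glycolysis and hypoxia were called higher (camera adjusted p = 0.000172), with 1 of 27 members up and 0 down (7 and 1 adjusted over the list alone). The adjusted p was 0.373 with an estimated correlation, and 0.0805 with fry, which tests the list against no change and not against other genes. The median log2 fold change of 0.33 was 0.14 without control replicate 1 and 0.22 after GC correction. Hexokinase 2 (HK2) was at 13.3 ± 0.358 against 5.68 ± 0.529 FPKM (log2 fold change 1.10, limma adjusted p = 0.00426), and PKM and VEGFA had log2 fold changes of 0.66 and 0.61 (0.0976 and 0.085). The unfolded protein and integrated stress response list was called higher (camera adjusted p = 0.00103), with 1 of 28 members up and 0 down (8 and 0 adjusted over the list alone) and an adjusted p of 0.292 with an estimated correlation. Its median log2 fold change of 0.21 was 0.13 without control replicate 1 or irradiated replicate 1. The member that rose, SESN2, also belongs to the p53 list and was at 10.4 ± 0.605 against 5.06 ± 1.09 FPKM (limma adjusted p = 0.0343). It passed in 1 of the 6 fits that left out 1 library (adjusted p up to 0.154). ASNS and PSAT1, enzymes of amino acid synthesis, had log2 fold changes of 0.51 and 0.64 (limma adjusted p = 0.052 and 0.0525), and both passed after GC correction (0.0204 and 0.0486).

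Mitochondrially encoded genes were called lower (camera adjusted p = 0.000495; adjusted p = 0.373 with an estimated correlation), with 13 of 13 members below 0 and a median log2 fold change of -0.38. This group moves with control replicate 1, the library in which they made up 24.1% of the FPKM total: without it the median was -0.24 (adjusted p = 0.0106), as it was without irradiated replicate 1 (0.00486), and with GC correction as well the list was not called without it (0.066). The adjusted p was 0.886 with quantile normalization, and 0.199 against no change (fry). limma called 0 members, with 4 at an unadjusted p under 0.05 and 0 in the authors' deposited table. MT-CO3 was at 3742 ± 396.2 against 4878 ± 515.6 FPKM, and MT-CO2 had a log2 fold change of -0.38 that became 0.03 with quantile normalization.

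The remaining lists were not called. The fry p-values beside them test a list against no change, not against other genes as camera does. In the type I interferon list (camera adjusted p = 0.234; 0.046 with fry) 1 of 23 members rose (2 adjusted over the list alone), IFI44, at 4.07 ± 0.535 against 1.59 ± 0.384 FPKM (limma adjusted p = 0.0244), which passed in 1 of the 6 fits that left out 1 library (up to 0.128). IFIT3 had a log2 fold change of 0.52 (limma adjusted p = 0.0976; 0.0165 after GC correction). In the list of epithelial junction and keratin genes (camera adjusted p = 0.281; 0.0329 with fry) 2 of 16 members rose (2 up and 1 down adjusted over the list alone): the laminin chain LAMB3 at 24.2 ± 1.29 against 5.62 ± 0.86 FPKM (log2 fold change 1.94, limma adjusted p = 0.00113) and the keratin KRT7 at 46.5 ± 6.38 against 23.3 ± 4.13, which passed in 1 of the 6 such fits (up to 0.151). In the apoptosis list (camera adjusted p = 0.234; 0.0389 with fry) 1 of 26 members rose (2 adjusted over the list alone), the death receptor TNFRSF10A at 11.5 ± 0.97 against 6.52 ± 0.853 FPKM (limma adjusted p = 0.0373), which passed in 0 of the 6 such fits (up to 0.149). BCL2L1 had 0.70 on the log2 scale (limma adjusted p = 0.0744; 0.0201 after GC correction). limma called 0 of 17 heat shock proteins, 0 of 33 nuclear-encoded respiratory chain genes and 0 of 44 ribosomal proteins (3, 1 and 0 at an unadjusted p under 0.05, and 0 in each list in the authors' deposited table; camera adjusted p = 0.234, 0.904 and 0.234). HSP90AB1 and HSF1 had log2 fold changes of 0.25 and 0.48, UQCRB and COX7C -0.26 and -0.22, and RPS19 and RPS13 0.56 and -0.25. COX7C was at 0.01 after GC correction. The ribosomal list was called higher without irradiated replicate 3 (adjusted p = 0.0289).

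Markers of other cell types were too few for a list test. Of the markers of secretory, ciliated and alveolar cells, fibroblasts, endothelium and leukocytes, 1, 4, 1 and 3 genes were tested, and limma called 0 of them over all genes (0, 1, 0 and 2 at an unadjusted p under 0.05, and 0 in the authors' deposited table). Adjusted over the list alone, 1 fibroblast marker fell, PDGFRB at 3.39 ± 0.422 against 5.31 ± 0.918 FPKM (limma adjusted p over all genes 0.122; 0.0118 after GC correction). The same adjustment called 2 leukocyte markers higher, CD68 at 7.22 ± 1.99 against 3.43 ± 0.84 FPKM and CORO1A at 2.00 ± 0.214 against 0.967 ± 0.443 (limma adjusted p over all genes 0.0895 and 0.125). THY1 was at 70.5 ± 5.21 against 57.0 ± 11.2 FPKM, ABCA3 at 8.81 ± 0.678 against 8.23 ± 0.396 and EGFL7 at 8.27 ± 1.57 against 5.75 ± 1.80; the log2 value of ABCA3 was 0.09, and -0.11 after GC correction.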

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

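The tests with corrections for GC content and length and with sample weights were chosen after the result was seen; the other settings were fixed before. Against 184 genes in the reported fit, limma called 157 to 212 with other pseudocounts, filters, normalizations or a robust trended fit, and 180 of the 184 stayed called with quantile normalization. The filter at a mean FPKM of 0.1 removed no gene, so it is the same setting as no filter. Counts moved further with a fold of at least 2 added (63 genes) and in the authors' deposited q-values (69). They also moved with the GC correction (412), with GC content and length corrected (499) and with sample weights, which gave 1341 genes by REML, an estimate that stopped before it converged, and 2000 gene by gene, so neither count is relied on. Leaving out 1 library gave 40 to 174 genes, and after GC correction 101 (119 and 101 without irradiated replicates 1 and 2) to 421; 35 genes (33 higher, 2 lower) were called whichever library was left out. Fewer samples and residual degrees of freedom tend to lower such counts. After GC correction, though, the count without control replicate 1 (421) was above that with all libraries (412). The cause of the other moves was not tested. The replicate number as a block gave 32 genes, and 85 with the GC correction. The numbers share no stated origin, and deviations of same-numbered samples correlated at -0.33, 0.07 and -0.30, so the numbers were not taken to pair samples; not every sample correlated best with its own number. The lists called numbered 10 as reported and 10 to 12 in the other settings, except with an estimated correlation. There 1 of the 21 lists was called (p53 targets), and 1 with GC correction as well. That test estimates the correlation in each list from the data, on the same samples, genes and lists. So 9 of the 10 list calls depended on the preset of 0.01, which takes a list's genes as nearly uncorrelated. Apart from CDKN2B, the text names 48 changed genes. Of these, 47 kept their call after GC correction, 47 with quantile normalization and 44 with a pseudocount of 0.1. With the replicate number as a block 23 kept it, and 25 without each library in turn. None of the 48 changed sign in these settings. The respiratory chain list turned below other genes with quantile normalization (mean log2 fold change -0.001), without irradiated replicate 1 (0.008), 2 (0.005) or control replicate 1 (-0.081), in a range of -0.081 to 0.090 over the libraries left out, and after GC correction without irradiated replicate 1 (0.009) or control replicate 1 (-0.072). The ribosomal list did so without control replicate 1 (-0.010; range -0.010 to 0.139), and after GC correction without irradiated replicate 1 (-0.001) or 2 (0.011) or control replicate 1 (-0.039). Signs of genes near 0 also turned: CCNB1 (-0.06 with quantile normalization), MCM2 (-0.007 with quantile normalization, -0.147 after GC correction, -0.099 without irradiated replicate 1, -0.109 without control replicate 1, up to 0.136 without others), HMOX1 (-0.101 without control replicate 1, up to 0.427 without others), CAT (0.015 after GC correction, 0.067 without irradiated replicate 1, 0.025 and 0.021 without control replicates 2 and 3, down to -0.146 without others), COX7C (0.006) and ABCA3 (-0.109) after GC correction, and MT-CO2 (0.030 with quantile normalization). The cause of these reversals was not tested. The depth is unknown, so what it limits cannot be stated.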

Other observations

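The 2 gene lists in this part and all tests but the counts of other splits without GC correction were chosen after the result was seen, and the genes named here outside the rule were chosen after their values were seen. A set of 10 genes that serves as a published score of output from the ERK pathway, which carries growth-factor signals, lay higher in irradiated cells. Of the 10 genes tested, 7 rose and 0 fell, and the median log2 fold change was 1.37. Beside CCND1, DUSP4 and DUSP6, the transcription factors ETV5 (11.7 ± 0.994 against 2.27 ± 0.204 FPKM, mean ± SD, n = 3) and ETV4 (4.004 ± 0.692 against 0.622 ± 0.0741), the feedback inhibitor SPRY4 (1.81 ± 0.115 against 0.306 ± 0.0976) and the receptor EPHA2 (41.0 ± 5.30 against 15.9 ± 2.33) rose (limma adjusted p = 0.000685, 0.00197, 0.00426 and 0.00877). EPHA2 lost its call without irradiated replicate 2 (adjusted p = 0.0572). DUSP4 and DUSP6 also belong to the list of immediate early genes. The camera adjusted p was 8.75e-12 over 23 lists, and 0.0327 with an estimated correlation, but it is not independent evidence, since the list was picked after these values were seen.

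Complement and acute-phase genes lay mostly lower: of 10 tested members 6 fell and 1 rose (7 and 2 adjusted over the list alone), with a median log2 fold change of -0.81. Over all genes, 3, 1 and 2 fell without irradiated replicate 1, 2 or 3, and 5, 2 and 3 without control replicate 1, 2 or 3. The camera adjusted p was 0.00106, and 0.182 with an estimated correlation. Beside C1S, CFB, CEBPD and SAA2, SAA1 was at 68.5 ± 8.68 against 114.6 ± 11.5 FPKM and C1RL at 3.03 ± 0.278 against 6.29 ± 0.264 (limma adjusted p = 0.0453 and 0.011). SAA1 passed in 0 of the 6 fits that left out 1 library (adjusted p up to 0.219), and also lost its call with a pseudocount of 0.1 (0.0625) and with quantile normalization (0.0542). C1RL lost its call without 2 of the libraries (up to 0.0731) and overlaps another listed gene. PTX3, a secreted pattern-recognition protein, was the member that rose, at 66.5 ± 1.46 against 26.0 ± 1.57 FPKM (limma adjusted p = 0.0017).

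The rise of the ERK output genes is a hypothesis about the pathway, and no phosphorylation was measured. The median was 1.23 after GC correction and 1.29 without control replicate 1. These checks had little room to come out otherwise, so no conclusion is drawn from them. The 10 genes were picked after their values were seen, and their mean GC content of 50.8% is near the 49.5% of all tested genes. The control libraries also lay close together, with means of 1.92, 1.98 and 2.06 over the list (log2). More cycling cells in the irradiated cultures would raise the replication and mitosis lists, whose mean log2 difference was -0.16 over 75 genes, lower in each irradiated library (4.84 to 4.93) than in each control library (5.00 to 5.07). Irradiation is a candidate explanation for the 1.37, but differences in density, medium or serum between the cultures were not tested and stay open.

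Fold changes followed transcript GC content (rho = 0.56 across 10462 genes, which are not independent replicates). Libraries of the same group also differed along GC content: irradiated replicate 1 deviated from the other irradiated libraries with rho = 0.68 and replicate 3 with -0.66, and control replicates 1 and 3 from theirs with -0.60 and 0.57. The lower of both groups' largest absolute values was 0.60, which is consistent with a bias between libraries that is not tied to the treatment. Control replicate 1 alone does not account for it, since rho was 0.37 without it. An effect of irradiation on the trend cannot be told apart from this bias: an exact two-sided permutation test of the 6 libraries' GC slopes gave p = 0.2, and 3 against 3 cannot go below 0.1.

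Large fold changes without a call may come partly from fragments divided between overlapping genes. Of 37 genes with a fold of at least 2 that did not pass, 40.5% (15 genes; exact 95% interval 24.8% to 57.9%) overlap another listed gene on the same strand, against 7.1% of all tested genes (Fisher's exact test, two-sided, p = 1.09e-08). The other 22 do not, and the interval spans 1 in 2 genes, the bound set for this test, so it leaves open how much of the group this explains. Overlapping genes can trade fragments, as NBL1 and MINOS1-NBL1 may, both among the 37. The genes are therefore not independent, and the p-value and interval may be too narrow. No biological explanation was tested for this group.

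Other splits of the 6 samples into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 184 genes, and 1 of the 10 splits called as many; the highest of the others called 4. After GC correction it called 412 (1 of 10 splits), against at most 8. For the gene lists, 4 of the 10 splits called as many as the real one: it called 10 of the 21 lists and the highest of the others 11. The 11 came from setting irradiated replicates 1 and 2 with control replicate 2, or with control replicate 3, against the rest. That leaves control replicate 1 and irradiated replicate 3 together. After GC correction the real split called 11 lists and the highest of the others 9.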
